A study of Homo sapiens with 11 samples.

How the data were processed

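Total RNA from hTert-HME1 cells, a human mammary epithelial line immortalised with telomerase, was depleted of ribosomal RNA and sequenced. The cells had been transfected with a control siRNA or a BRCA2 siRNA and grown in mammary epithelial medium with or without epidermal growth factor (EGF). The labels give 11 libraries at passage 6, with biological replicates named A, B and C. There were 3 control libraries with EGF, 3 BRCA2 siRNA libraries with EGF, 2 control libraries without EGF (A and C) and 3 BRCA2 siRNA libraries without EGF. Groups are named by their labels throughout. Each target had a single siRNA, so effects of that sequence on other transcripts cannot be separated from effects on BRCA2.

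The authors deposited a single table of 40460 Ensembl genes by 11 libraries in log2 units, with values from -2.94 to 20.62. The submitters' processing notes name the hg19 build, TopHat2 2.0.11, DESeq2 and limma, without a role or an order. The read counter, the annotation and the transform behind the log2 values are not given in the sources used here. Genes with few reads sit at a floor that differs from gene to gene, so fold changes of weakly expressed genes may be compressed by a transform that cannot be checked. The deposited table holds no counts, so the depth of each library is unknown from it, and no interval or detection floor that needs counts is given.

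In each of the 40460 genes the mean over the 4 replicate A libraries equalled the mean over the 7 replicate B and C libraries, with a largest difference of 7.2e-09. The deposited values had therefore been centred for A against B and C, a step the sources used here do not name. Control siRNA without EGF has no replicate B, so the make-up by group differs between A and the rest. With equal means in all genes, the centring took no account of the groups. It shifted A values by part of the group differences, and the main fit carries that shift. This step also uses up information that the model below does not count. A fit with a term for replicate A, which takes up such a shift, was therefore added as an alternative. Another alternative added for this reason used only the libraries of replicates B and C.

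Gene symbols were matched to the Ensembl identifiers through a RefSeq gene table of a later build, which gave a symbol to 37585 genes (92.9%). Because the builds differ, no coordinates are given.

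The design was written before the data were examined. It provided for values already on a log scale, which were then used as they were, with no pseudocount. Genes with a value of at least 10 on the linear scale (3.32 on the log2 scale) in at least 2 libraries were tested, which left 17945 genes. A linear model with the 4 groups was fitted to all 11 libraries in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and a mean-variance trend. The fit has 7 residual degrees of freedom, and groups share the estimate of spread. The contrasts were the BRCA2 siRNA effect with EGF and without EGF, the EGF withdrawal effect with each siRNA, and the interaction. The interaction is the withdrawal effect with BRCA2 siRNA minus that with control siRNA. Tests were two-sided, adjusted p values follow Benjamini and Hochberg within a comparison, and the threshold was 0.05. Errors after ± are moderated standard errors on the log2 scale. The BRCA2 contrasts share libraries with the withdrawal contrasts, so their chance errors are shared too.

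The named genes followed a rule fixed in the design. BRCA2 came first. Then came up to 8 genes with the largest rise and 8 with the largest fall in each comparison, among genes past the threshold with a symbol. Their mean in the higher group had to exceed the median gene, and every library of one group had to lie above every library of the other, a condition not set for the interaction. For each gene list, up to 4 members with the smallest p in a comparison could be named. The text names some of these members, picked from within that rule after their values were seen.

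The 22 gene lists were written from textbook knowledge before the data were examined, and 562 of their 604 genes were in the table. They cover MAPK feedback and immediate-early genes, EGF receptor family and ligands, DNA replication and S phase, mitosis and G2/M, p53 targets, homologous recombination and Fanconi anaemia, interferon-stimulated genes, NF-kB and inflammatory cytokines, ATF4 and unfolded protein response, FOXO targets and quiescence, glycolysis and hypoxia response, sterol synthesis, replication-dependent histones, ribosomal proteins and mitochondrially encoded mRNAs. They also cover TGF-beta and YAP targets, the type IV and V collagen and laminin matrix, and markers of basal epithelial cells, luminal mammary epithelial cells, cornified envelope and keratinocyte differentiation, fibroblasts and mesenchymal cells, and leukocytes and endothelial cells. Each list was tested with camera in limma at its preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

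Alternative settings chosen in the design were no filter, a stricter filter of at least 50 on the linear scale, median-of-ratios rescaling, quantile normalization, robust empirical Bayes, a replicate block, a fit of only the groups compared, and leaving out each library in turn. One more alternative, added after the data were seen, took the first principal component of the model's residuals as a covariate. The model was tested on simulated data with the same groups and each gene's pooled spread. It recovered 71% to 73% of genes changed by 1 log2 unit in the 4 pairwise comparisons and 48% in the interaction. With no simulated change it called 0 genes in each comparison. The simulated noise was independent between libraries and equal in all groups. In the data, libraries of the letters B and C with EGF share a deviation by letter, and B and C differed more with EGF than without. Which group had the widest spread differed from gene to gene. These rates may therefore not hold for the data.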

Results

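Gene expression was measured by sequencing of total RNA in 11 libraries of the immortalised human mammary epithelial line hTert-HME1. The cells carried a control siRNA or an siRNA against BRCA2, a gene of homologous recombination, and grew with or without EGF, the growth factor of their usual medium. There were 3 control and 3 BRCA2 siRNA libraries with EGF, and 2 control and 3 BRCA2 siRNA libraries without EGF. The depth of the libraries is unknown, since the deposited values are on a log2 scale with no counts. The design crosses siRNA with EGF, so it asks how each siRNA changes expression in either medium and how EGF withdrawal changes it under either siRNA. EGF status set the libraries apart on the first principal component, which held 65.9% of the variance. On it the 6 libraries with EGF lay between -41.05 and -15.62, the 3 BRCA2 siRNA libraries without EGF between 10.66 and 31.18, and the 2 control libraries without EGF at 64.96 and 65.81.

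BRCA2 (ENSG00000139618) itself was not lower in the libraries labelled BRCA2 siRNA. With EGF its log2 value was 12.37 to 12.43 in these libraries and 12.13 to 12.48 in the control libraries, a log2 difference of 0.05 ± 0.12 (n = 3 and 3, adjusted p = 0.999). Without EGF it was higher in the libraries labelled BRCA2 siRNA, by 0.74 ± 0.13 on the log2 scale or 1.67-fold (n = 3 and 2, adjusted p = 0.00397). The values were 12.11 to 12.48 against 11.44 and 11.65. EGF withdrawal changed BRCA2 by -0.81 ± 0.13 with control siRNA (adjusted p = 0.000444) and by -0.12 ± 0.12 with BRCA2 siRNA (adjusted p = 0.468), and the test of the difference gave an adjusted p of 0.0532. Within replicate A the BRCA2 siRNA difference was -0.01 with EGF and 1.04 without, and within replicates B and C it was 0.08 and 0.54. The call without EGF ended when control replicate A without EGF was left out (0.64, adjusted p = 0.0655) and with only replicates B and C (adjusted p = 0.382).

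**Figure D1:**
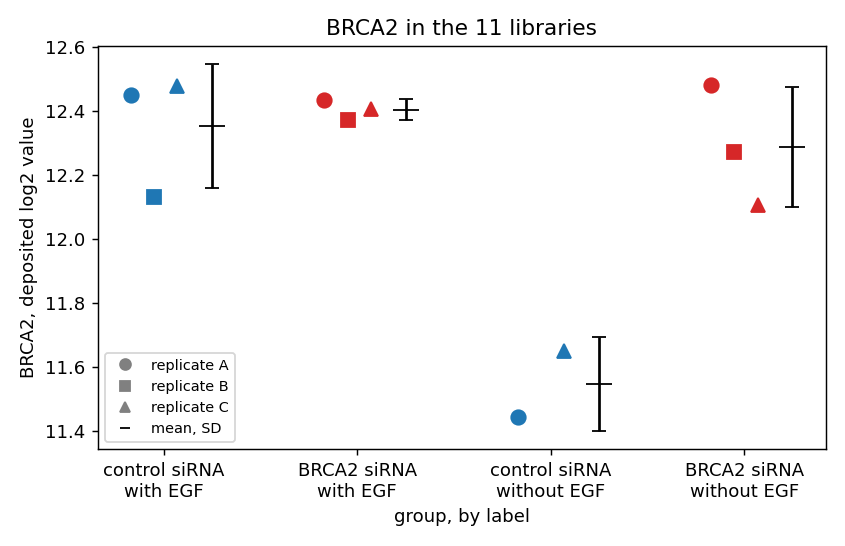
Deposited log2 value of BRCA2 in each of the 11 libraries, by siRNA label and EGF, with the mean and SD of each group; symbols mark the replicate letter. The 3 libraries labelled BRCA2 siRNA with EGF lie at 12.37 to 12.43, within the range of the control libraries (12.13 to 12.48), and the 2 control libraries without EGF are the lowest, at 11.44 and 11.65.

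The comparison of EGF withdrawal under control siRNA asks what these cells express without their growth factor. GPNMB (ENSG00000136235), a transmembrane glycoprotein of lysosomes and melanosomes, rose 46.4-fold (5.54 ± 0.36, n = 2 and 3, adjusted p = 7.05e-06). The ephrin receptor EPHB6 (ENSG00000106123) rose by 5.00 ± 0.39 on the log2 scale, the protease inhibitor SERPINB13 (ENSG00000197641) by 4.90 ± 0.39 and the apolipoprotein APOE (ENSG00000130203) by 4.50 ± 0.31. TRIM29, the epidermal protease KLK5, the drug-metabolising enzyme FMO2 and the death ligand TNFSF10 rose by 4.73, 4.72, 4.23 and 3.99. The collagenase MMP1 (ENSG00000196611) fell most among the genes named by the rule, by 4.16 ± 0.29 on the log2 scale (adjusted p = 7.05e-06). CHAC1, a glutathione-degrading enzyme, changed by -3.85, DMBT1 by -3.82, the decoy receptor IL13RA2 by -3.61, INSC by -3.36, the hair keratin KRT34 by -3.28, the glycerolipid enzyme GPAT3 by -3.04 and OSBP2 by -2.92. In total 9121 of the 17945 genes tested passed the threshold, 4439 higher and 4682 lower without EGF, of which 2312 changed at least 2-fold. The share that rose depended on the filter: 48.7% here, 55.6% with no filter and 39.5% under the stricter filter. It was 56.5% with only replicates B and C.

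Most mitosis and histone genes fell under control siRNA, and some genes of DNA replication and homologous recombination. Over all 17945 genes tested 4682 fell and 4439 rose, and the list counts of this comparison stand beside these. For DNA replication the share that fell was close to that of all genes. In the mitosis list 30 of 33 members fell (30 adjusted over the list alone), among them the kinase AURKA (-1.39), the ubiquitin ligase activator CDC20 (-1.53), UBE2C (-1.18) and the cyclin CCNB2 (-1.09). The list's median was -0.96 (camera adjusted p = 8.8e-13; adjusted p = 0.38 with an estimated correlation). Of 25 replication-dependent histones 18 fell (18 adjusted over the list alone), such as H4C11 (-1.32) and H1-2 (-0.86; -0.56 under quantile normalization), with a camera adjusted p of 1.8e-06 and an adjusted p of 0.51 with an estimated correlation. In the DNA replication list 10 of 37 fell (10 adjusted over the list alone), including the replication initiation factors CDC45 (-1.50) and CDC6 (-1.05), and 27 did not pass the test. Its camera adjusted p was 0.0052 (0.0593 under the stricter filter, 0.0577 with only replicates B and C), and the adjusted p was 0.66 with an estimated correlation. In the homologous recombination list 15 of 35 fell and 2 rose (15 and 2 adjusted over the list alone), with RAD51C at -0.83 and FANCD2 at -0.73. Its camera adjusted p of 0.013 became 0.107 under the stricter filter, 0.175 under quantile normalization and 0.0691 with only replicates B and C, and the adjusted p was 0.66 with an estimated correlation.

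Some transcriptional targets of growth factor and stress signalling changed as well. Of 25 MAPK feedback and immediate-early genes 13 fell and 4 rose (13 and 4 adjusted over the list alone). The feedback inhibitor SPRY4 changed by -1.90 and the ETS factors ETV4 and ETV5 by -2.45 and -2.33. FOSB, an immediate-early factor, rose by 2.67 ± 0.26. The camera adjusted p of 0.048 became 0.107 under the stricter filter, 0.175 under quantile normalization, 0.0777 in the groups compared alone and 0.2 with only replicates B and C, and the adjusted p was 0.66 with an estimated correlation. Among 12 genes of the EGF receptor family 5 fell and 3 rose (5 and 3 adjusted over the list alone). The ligands AREG and TGFA changed by -1.79 and -1.46, and the receptors ERBB2 and ERBB3 by 0.59 and 0.80. With only replicates B and C these 4 calls were lost, at -1.72, -1.32, 0.58 and 0.75 (adjusted p = 0.0552, 0.0565, 0.0848 and 0.121). The list as a whole did not pass (camera adjusted p = 0.38). In the ATF4 and unfolded protein response list 21 of 27 fell (21 adjusted over the list alone), with ATF4 at -1.44 and the chaperones PDIA4 and CALR at -0.89 and -0.69 (camera adjusted p = 8.6e-06; adjusted p = 0.53 with an estimated correlation). Among 28 p53 targets 17 fell and 2 rose (18 and 2 adjusted over the list alone), including the ribonucleotide reductase subunit RRM2B (-1.18), TIGAR (-1.21) and the nuclease AEN (-1.37). Their camera adjusted p was 0.0056 (0.0573 under the stricter filter), with an adjusted p of 0.38 with an estimated correlation. Of 18 NF-kB and cytokine genes 8 fell (8 adjusted over the list alone), such as CSF3 (-1.58 ± 0.17) and IL6 (-2.80 ± 0.78). The adjusted p of IL6 rose from 0.0113 to 0.0663 without control replicate A without EGF and to 0.0503 without control replicate C without EGF. The list had a camera adjusted p of 0.013 (0.0818 under the stricter filter, 0.0681 with only replicates B and C), and an adjusted p of 0.66 with an estimated correlation. Both the ATF4 list and the NF-kB list also differed among the libraries with EGF, with medians 0.84 and 1.38 higher in replicate B than in replicate C. So did other lists: the median B minus C was -0.90 for DNA replication, -0.72 for sterol synthesis, -0.56 for histones, -0.34 for homologous recombination, 0.84 for the EGF receptor family, 0.40 for basal markers and 0.34 for MAPK genes.

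FOXO targets, genes induced when growth factor signalling drops, rose in 16 of 25 cases (16 adjusted over the list alone), among them the ubiquitin ligase FBXO32 by 3.64 ± 0.30, SESN3 by 1.99 and the insulin receptor INSR by 1.56. Their camera adjusted p was 2.1e-05, and the adjusted p was 0.38 with an estimated correlation. In the glycolysis list 16 of 28 fell and 3 rose (16 and 4 adjusted over the list alone), with PFKP at -0.98, ENO1 at -0.77 and the glucose transporter SLC2A1 at 1.29. In the sterol synthesis list 10 of 25 fell (10 adjusted over the list alone), with ACAT2 at -1.42 and FDPS at -0.99. The camera adjusted p values of both, 0.0052 and 0.028, rose to 0.0747 and 0.185 under quantile normalization. The sterol list had 0.143 under the stricter filter and 0.104 with only replicates B and C. With an estimated correlation the adjusted p values were 0.53 and 0.66.

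Most cornified envelope and basal markers rose under control siRNA, while luminal markers went both ways. Of 17 cornified envelope and keratinocyte genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 2.34. The transglutaminase TGM1 rose by 3.43 ± 0.32, the keratin KRT4 by 2.37 and filaggrin, FLG, by 2.34 (camera adjusted p = 0.00014; adjusted p = 0.36 with an estimated correlation). Of 23 basal epithelial markers 13 rose and 2 fell (13 and 2 adjusted over the list alone), with KRT16 at 2.95, the anchoring collagen COL7A1 at 1.68 and KRT14 at 1.37 (camera adjusted p = 0.00025; adjusted p = 0.51 with an estimated correlation). Of 29 interferon-stimulated genes 17 rose and 2 fell (18 and 2 adjusted over the list alone), including IFIT2 by 2.47 and the RNA sensor IFIH1 by 1.67 (camera adjusted p = 3.6e-05; adjusted p = 0.36 with an estimated correlation). Markers of fibroblasts and mesenchymal cells rose in 11 of 22 cases and fell in 5 (12 and 6 adjusted over the list alone), with the collagens COL1A1 at 3.05 ± 0.24 and COL3A1 at 2.32 and the matrix protein POSTN at 2.03 (camera adjusted p = 0.048; adjusted p = 0.49 with an estimated correlation). Among luminal markers 5 of 13 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of -0.18 and a mean of 0.15. Among the 4 measured leukocyte and endothelial markers KDR and CD14 rose by 2.51 and 2.00 and 1 fell (2 and 1 adjusted over the list alone). Of 22 type IV and V collagen and laminin genes 8 rose and 5 fell (8 and 6 adjusted over the list alone). Of 18 TGF-beta and YAP targets 5 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of -0.07 and a mean of 0.03. Of 13 mitochondrially encoded mRNAs 4 rose (3 adjusted over the list alone). Of 34 ribosomal protein genes 1 rose and 1 fell (1 and 0 adjusted over the list alone). The luminal, leukocyte, matrix, TGF-beta, mitochondrial and ribosomal lists did not pass camera in this comparison (adjusted p from 0.071 to 0.99). Quantile normalization called the matrix (0.0142), mitochondrial (0.00337) and ribosomal (0.00073) lists. The mitochondrial list also passed with no filter (0.0311), the stricter filter (0.0365) and the groups compared alone (0.0334), and the matrix list with the stricter filter (0.0355). With only replicates B and C the count of genes past the threshold was 2074, against 9121, and 8 of 63 named calls were lost. Some list medians were then nearer 0: -0.72 for NF-kB genes (-1.30 with all libraries), -0.26 for DNA replication (-0.45), -0.23 for MAPK genes (-0.43) and -0.30 for sterol synthesis (-0.49). With no filter the medians were 0.68 for cornified envelope genes (2.34), 0.49 for interferon-stimulated genes (0.85), 0.35 for fibroblast markers (0.56) and -0.69 for NF-kB genes.

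The same withdrawal in the libraries labelled BRCA2 siRNA asks whether the response differs when the BRCA2 siRNA is present. FABP4, a fatty acid carrier, rose 6.98-fold (2.80 ± 0.26, n = 3 and 3, adjusted p = 0.000197) and APOE 6.72-fold (2.75 ± 0.28). The complement protease C1R rose by 2.36 on the log2 scale, the metalloprotease TLL1 by 2.32, TRIM29 by 2.31, the Notch ligand DLL1 by 2.23, the teneurin TENM2 by 2.20 and the cadherin FAT2 by 2.16. DMBT1 changed by -2.88 ± 0.48, MMP1 by -2.85 ± 0.26, IL13RA2 by -2.53, the axon guidance factor SEMA3A by -2.27, GPAT3 by -1.98, the G protein regulator RGS2 by -1.78 and VEPH1 by -1.70. The stress cytokine GDF15 changed by -1.72 ± 0.56 with an adjusted p of 0.0434, which became 0.0596 with a term for replicate A. A total of 4871 genes passed, 2397 higher and 2474 lower, and 467 changed at least 2-fold. The share that rose was 49.2%, 51.7% with no filter and 42.1% under the stricter filter.

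Some mitosis, histone, p53 and differentiation genes changed with BRCA2 siRNA too. In the mitosis list 15 of 33 fell (20 adjusted over the list alone), with AURKA and HMMR both at -0.69 (camera adjusted p = 3.2e-06; adjusted p = 0.61 with an estimated correlation). Among p53 targets 13 of 28 fell (17 fell and 1 rose adjusted over the list alone), with RRM2B at -0.99, the cell cycle inhibitor CDKN1A at -0.92 and MDM2 at -0.62 (camera adjusted p = 3.4e-06; adjusted p = 0.24 with an estimated correlation). Of 25 histones 9 fell (16 adjusted over the list alone), with H4C3 at -0.83. Of 27 ATF4 and unfolded protein response genes 5 fell (3 adjusted over the list alone), with ATF4 at -0.50. Their camera adjusted p values were 5.5e-06 and 0.0014, and the adjusted p values were 0.61 and 0.64 with an estimated correlation. Of 37 DNA replication genes 3 fell (2 adjusted over the list alone), with CDC45 at -0.57, and the list did not pass (median 0.08, camera adjusted p = 0.90 with the direction down). Among cornified envelope genes 8 of 17 rose (9 adjusted over the list alone), with KLK5 at 2.67 and the calcium-binding proteins S100A9 and S100A8 at 2.04 and 1.76 (camera adjusted p = 0.00045; adjusted p = 0.40 with an estimated correlation). Of 23 basal markers 10 rose and 2 fell (11 and 2 adjusted over the list alone), with COL7A1 at 1.11. Of 22 fibroblast markers 8 rose and 4 fell (8 and 4 adjusted over the list alone), with the smooth muscle protein TAGLN at 1.68. Both passed camera (adjusted p = 0.00088 and 0.037), with adjusted p values of 0.61 and 0.60 with an estimated correlation. Of 29 interferon-stimulated genes 8 rose and 2 fell (9 and 3 adjusted over the list alone), with IFIT2 at 1.19, DTX3L at 0.70 and the exonuclease ISG20 at -1.10 (camera adjusted p = 0.011; adjusted p = 0.60 with an estimated correlation).

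MAPK feedback genes fell in 9 of 25 cases and rose in 3 (9 and 3 adjusted over the list alone), with SPRY2 at -1.17, ETV4 and ETV5 both at -0.86 and SPRED1 at -0.55. The camera adjusted p of 0.036 became 0.109 under the stricter filter, 0.111 under quantile normalization and 0.288 with only replicates B and C, and the adjusted p was 0.64 with an estimated correlation. For NF-kB genes 2 of 18 fell (0 adjusted over the list alone) and the camera adjusted p of 0.037 became 0.133, 0.0671 and 0.12 under these settings, with an adjusted p of 0.64 with an estimated correlation. FOXO targets rose in 3 of 25 cases (3 adjusted over the list alone), including FBXO32 by 1.83, and the list did not pass (camera adjusted p = 0.13, but 0.0225 under quantile normalization, 0.0459 under the stricter filter and 0.0357 with only replicates B and C). Mitochondrially encoded mRNAs rose in 9 of 13 cases (11 adjusted over the list alone), with MT-ND1 at 0.89 and MT-CYB at 0.80 (camera adjusted p = 3.2e-06; adjusted p = 0.60 with an estimated correlation). Of 34 ribosomal protein genes 14 fell and 1 rose (21 and 1 adjusted over the list alone), with RPS20 at -0.33 and RPS23 at -0.30. Their median of -0.26 became -0.08 under quantile normalization, where the camera adjusted p went from 3.2e-06 to 0.0993, and with an estimated correlation the adjusted p was 0.64. Without BRCA2 siRNA replicate A with EGF, the calls of GDF15 (-1.68, adjusted p = 0.118), ATF4 (-0.47, 0.0688), CDC45 (-0.50, 0.0595), RPS20 (-0.29, 0.0698) and RPS23 (-0.28, 0.0692) were lost. Without any 1 library the values of the 53 named genes past the threshold were 0.719 to 1.30 times those with all. Under quantile normalization ATF4 (-0.28, 0.0753), RPS20 (-0.14, 0.137) and RPS23 (-0.15, 0.135) lost their calls too. The count of 4871 genes fell to 2228 without BRCA2 siRNA replicate A with EGF, and was 2646 and 2861 without BRCA2 siRNA replicates C and B without EGF. With only replicates B and C it was 47.

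The interaction tests the difference between the withdrawal responses directly. GPNMB rose less with BRCA2 siRNA than with control siRNA, an interaction of -3.32 ± 0.48 (adjusted p = 0.0167). Its standard deviation was 0.79 among the BRCA2 siRNA libraries without EGF and 0.13 to 0.29 in the other groups, which the error pools. The interaction was also negative for EPHB6 (-3.26 ± 0.52), CYP1A1, a target of the aryl hydrocarbon receptor (-2.69), the carbonic anhydrase CA2 (-2.63), the prostaglandin-degrading enzyme HPGD (-2.57), TRIM29 (-2.42), SERPINB13 (-2.37) and PPFIBP2 (-2.28). On the positive side stood the ubiquitin ligase MARCHF4 (1.89 ± 0.24), the branched-chain aminotransferase BCAT1 (1.84 ± 0.34), KIAA1549L (1.78), INSC (1.77), the phosphodiesterase PDE2A (1.69), ETV4 and SPRY4 (both 1.59) and RPSAP52 (1.53), a transcript annotated as a pseudogene, whose reads may be shared with its parent gene. In total 595 genes passed, 248 positive and 347 negative. The share with a positive value was 41.7%, 28.8% with no filter and 48.3% under the stricter filter. Of the 1504 genes that rose at least 2-fold with control siRNA, 1470 had the same sign with BRCA2 siRNA and 1491 had a smaller change, with medians of 1.36 and 0.68. For the 808 that fell at least 2-fold the medians were -1.25 and -0.65, and 802 had the same sign. These genes were picked for a large change with control siRNA, which by itself favours a smaller value in the other group. TENM2, SEMA3A and RGS2 had interactions of 0.00 (95% interval -0.39 to 0.40), -0.01 (-0.48 to 0.46) and -0.00 (-0.40 to 0.40).

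Among the lists, 13 of 33 mitosis genes had a positive interaction (30 adjusted over the list alone), such as CDC20 (1.04) and PLK1 (0.78), with a camera adjusted p of 2.2e-17 and an adjusted p of 0.29 with an estimated correlation. Of 17 cornified envelope genes 7 were negative (10 negative and 1 positive adjusted over the list alone), with the desmosomal cadherin DSG1 at -3.07 and KRT4 at -2.00. Of 25 FOXO targets 7 were negative (14 adjusted over the list alone), with the kinase PDK4 at -2.53 and PIK3IP1 at -1.77. Of 29 interferon-stimulated genes 4 were negative (11 adjusted over the list alone), with RSAD2 at -1.58 and IFI44L at -1.57. These 3 lists passed camera (adjusted p = 3.3e-05, 1.2e-08 and 1.2e-06), and with an estimated correlation the adjusted p was 0.16 for each. Of 23 basal markers 5 were negative (9 adjusted over the list alone), with KRT16 at -1.98 and KRT15 at -1.94, and 2 of 27 ATF4 and unfolded protein response genes were positive (9 adjusted over the list alone), with ATF4 at 0.95. Both passed camera (adjusted p = 0.00013 and 3.1e-06), with an adjusted p of 0.53 with an estimated correlation for both. The interaction count was 0 when control replicate A with EGF, control replicate A or C without EGF, or BRCA2 siRNA replicate C with EGF was left out (limma; 2684 to 3400 genes at unadjusted p under 0.05), and 0 with only replicates B and C (limma; 990 genes at unadjusted p under 0.05). GPNMB stayed at -3.23 to -3.42 in the first 4 of these. The count was 1 without BRCA2 siRNA replicate B without EGF, 62 without its replicate A and 1040 without its replicate C, 157 without BRCA2 siRNA replicate A with EGF, and 1606 without control replicate C with EGF. A replicate block gave 930.

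**Figure D2:**
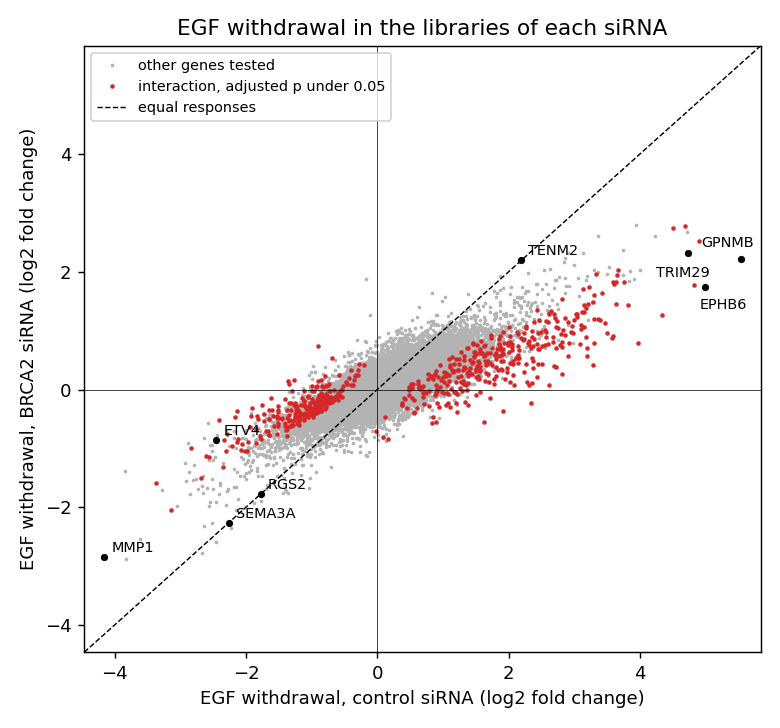
Log2 fold change on EGF withdrawal with control siRNA (horizontal) and with BRCA2 siRNA (vertical) for the 17945 genes tested; red points passed the interaction test, black points are genes named in the text whether or not they passed, and the dashed line marks equal responses. Of the 595 genes that passed, 248 lie above the line and 347 below. GPNMB reached 5.54 with control siRNA and rose less with BRCA2 siRNA, and TENM2, SEMA3A and RGS2 lie on the line.

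Across genes the withdrawal effects had a Pearson correlation of 0.83 (jackknife error over libraries 0.0716) and a Spearman correlation of 0.82, with a slope of 0.49 for BRCA2 siRNA on control siRNA. Genes are not independent replicates, so no p is given. The correlation was 0.66 within replicate A and 0.82 within replicates B and C. Shared calls numbered 1967 higher and 2190 lower, where independent lists would share 593 and 645, and 6 and 7 genes were called in opposite directions.

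The comparison of siRNAs without EGF had the question of what the BRCA2 siRNA changes in cells that lack the factor; it uses the same 2 control libraries as the withdrawal comparison. CHAC1 was 5.55-fold higher with BRCA2 siRNA (2.47 ± 0.49, n = 3 and 2, adjusted p = 0.0069) and BCAT1 4.02-fold higher (2.01 ± 0.26). ANGPTL4, an inhibitor of lipoprotein lipase, was higher by 1.73, KIAA1549L and MARCHF4 by 1.71, the serine synthesis enzyme PSAT1 by 1.70, asparagine synthetase, ASNS, by 1.69 and PDE2A by 1.63. GPNMB was lower (-3.21 ± 0.36, adjusted p = 0.00108), as were EPHB6 (-2.98 ± 0.39), CYP1A1 (-2.67), SERPINB13 (-2.65), MAL2 (-2.43), the proline-degrading enzyme PRODH (-2.37), CA2 (-2.34) and TRIM29 (-2.32). In total 3687 genes passed, 2007 higher and 1680 lower. The share higher was 54.4%, 61.7% under the stricter filter, 43.8% with no filter and 39.4% without control replicate A without EGF. Of the 3687 genes 550 differed at least 2-fold, of which 436 were lower. Without control replicate A without EGF, the calls of CHAC1 (2.33, adjusted p = 0.0735), PSAT1 (1.70, 0.0923) and ASNS (1.67, 0.151) were lost. Without any 1 library the values of the 59 named genes past the threshold were 0.711 to 1.29 times those with all libraries.

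Most mitosis genes, and some of DNA replication, histones and homologous recombination, were higher with BRCA2 siRNA in medium without EGF. Of 33 mitosis genes 30 were higher (32 adjusted over the list alone), with CDC20 at 0.97 and PLK1 at 0.81 (camera adjusted p = 5.3e-18; adjusted p = 0.27 with an estimated correlation). Of 37 DNA replication genes 11 were higher (22 adjusted over the list alone), with CDC6 and CDC45 both at 1.02. Of 25 histones 11 were higher (22 adjusted over the list alone), with H1-4 at 0.78. Their camera adjusted p values were 3.7e-09 and 3.6e-09, and the adjusted p values were 0.52 and 0.44 with an estimated correlation. Of 35 homologous recombination genes 14 were higher and 1 lower (18 and 1 adjusted over the list alone), with RAD51AP1 at 0.63 and FANCD2 at 0.58 (camera adjusted p = 0.00011; adjusted p = 0.52 with an estimated correlation). In the ATF4 and unfolded protein response list 12 of 27 were higher (13 adjusted over the list alone), with ATF4 at 0.92 and PDIA4 at 0.65 (camera adjusted p = 3.7e-05; adjusted p = 0.52 with an estimated correlation). Of 28 glycolysis genes 14 were higher and 2 lower (16 and 2 adjusted over the list alone), with PFKP at 0.66, GAPDH at 0.52 and SLC2A1 at -0.86 (camera adjusted p = 5.5e-05; adjusted p = 0.44 with an estimated correlation). Of 25 sterol synthesis genes 4 were higher (3 adjusted over the list alone), with ACAT2 at 0.76 (camera adjusted p = 0.003; adjusted p = 0.66 with an estimated correlation). Without control replicate A without EGF, the calls of RAD51AP1 (0.49, adjusted p = 0.12), FANCD2 (0.52, 0.0789), H1-4 (0.69, 0.0669), GAPDH (0.47, 0.0893) and ACAT2 (0.61, 0.172) were lost. Among MAPK genes 6 of 25 were higher and 3 lower (6 and 4 adjusted over the list alone), with SPRY4 at 1.48, ETV4 at 1.38 and FOSB at -2.21, and the list did not pass (camera adjusted p = 0.24, but 0.045 with no filter).

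FOXO targets were lower in 15 of 25 cases (16 adjusted over the list alone), with FBXO32 at -2.06, PIK3IP1 at -1.82 and the cyclin CCNG2 at -0.82 (camera adjusted p = 5.5e-09; adjusted p = 0.27 with an estimated correlation). Interferon-stimulated genes were lower in 11 of 29 cases (11 adjusted over the list alone), with RSAD2 at -1.96 and IFI44L at -1.59 (camera adjusted p = 2.4e-05; adjusted p = 0.27 with an estimated correlation). Of 17 cornified envelope genes 9 were lower and 3 higher (9 and 3 adjusted over the list alone), with DSG1 at -3.35 ± 0.47 and the protease KLK7 at -2.57 (camera adjusted p = 0.00052; adjusted p = 0.27 with an estimated correlation). Of 23 basal markers 9 were lower (11 adjusted over the list alone), with KRT15 at -2.13 and KRT16 at -1.84 (camera adjusted p = 0.0004; adjusted p = 0.52 with an estimated correlation). Ribosomal protein genes had 0 of 34 members past the threshold (0 adjusted over the list alone) and a median of -0.17, with a camera adjusted p of 0.0016 and an adjusted p of 0.66 with an estimated correlation. KRT8, a luminal keratin, was lower (-0.76), and so were the fibroblast collagen COL3A1 (-0.91) and KDR (-1.89). The calls of COL3A1 (-0.81, adjusted p = 0.0599) and KDR (-1.77, 0.0535) were lost without control replicate C without EGF. The luminal, fibroblast and leukocyte lists did not pass camera (adjusted p = 0.14, 0.42 and 0.26). The count of 3687 genes was 624 and 1182 without control replicates A and C without EGF, and 1662 and 2048 without BRCA2 siRNA replicates A and B without EGF. With only replicates B and C it was 0 (limma; 2070 genes at unadjusted p under 0.05), and in a fit of the groups compared alone it was 6776.

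**Figure D3:**
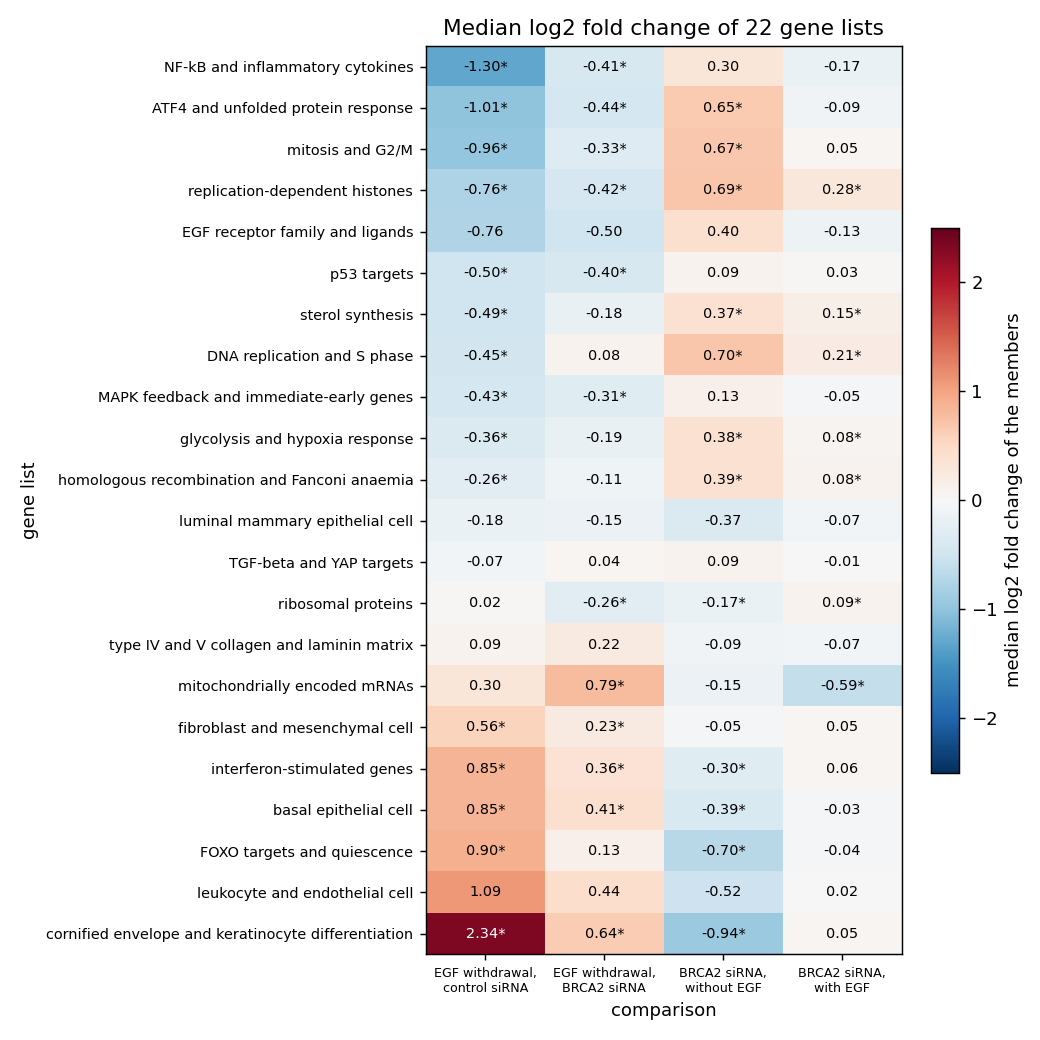
Median log2 fold change of the measured members of each of the 22 gene lists (vertical axis) in the 4 pairwise comparisons (horizontal axis); an asterisk marks a camera adjusted p under 0.05 at the preset correlation, and with an estimated correlation no list passed in these comparisons. Median changes run from -1.30 for NF-kB genes to 2.34 for cornified envelope genes on EGF withdrawal with control siRNA (-0.69 and 0.68 with no filter), and from -0.59 to 0.28 between siRNAs with EGF; under quantile normalization the ribosomal median of -0.26 on withdrawal with BRCA2 siRNA became -0.08.

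The comparison of siRNAs with EGF asks what the BRCA2 siRNA changes in the usual medium, and 1 of 17945 genes passed. MTATP8P1 (ENSG00000240409), a nuclear pseudogene copy of the mitochondrial gene MT-ATP8 that can share reads with it, was lower with BRCA2 siRNA (-1.39 ± 0.15, n = 3 and 3, adjusted p = 0.0252). It falls outside the rule for named genes and was chosen after its values were seen. Its log2 values were 3.53 to 3.98 against 5.01 to 5.26 in control libraries. Without EGF this gene was also called lower with BRCA2 siRNA, at 4.29 to 4.45 against 5.14 and 5.29. Mitochondrially encoded mRNAs had 0 of 13 members past the threshold over all genes and 10 lower adjusted over the list alone, with a median of -0.59. MT-ND4 stood at -0.73 ± 0.15 (adjusted p = 0.775) and MT-ND5 at -0.70 ± 0.11 (adjusted p = 0.336). The list passed camera (adjusted p = 1.8e-22), with an adjusted p of 0.14 with an estimated correlation. Medians were 0.28 for histones and 0.21 for DNA replication genes, with 0 members past the threshold in either list (0 adjusted over the list alone). H4C8 stood at 0.31 ± 0.14 and MCM5 at 0.21 ± 0.15 (adjusted p = 0.999 for both). Their camera adjusted p values were 1.7e-11 and 3e-06, and with an estimated correlation the adjusted p was 0.84 for both. Ribosomal, homologous recombination, glycolysis and sterol lists also passed camera, with medians of 0.09, 0.08, 0.08 and 0.15 and 0 members past the threshold (0 adjusted over the list alone; adjusted p = 0.84 with an estimated correlation). The glycolysis and sterol calls were lost under quantile normalization (adjusted p = 0.169 and 0.128), the groups compared alone (0.0606 and 0.0611) and only replicates B and C (0.277 for both). The sterol call was also lost under the stricter filter (0.064) and robust moderation (0.0515), and the homologous recombination call with only replicates B and C (0.103). Within the libraries with EGF, replicates B and C differed in these lists too, with a median B minus C of -0.90 for DNA replication, -0.72 for sterol synthesis, -0.56 for histones and -0.34 for homologous recombination. It was -0.24 for mitochondrially encoded mRNAs, -0.15 for glycolysis and 0.17 for ribosomal proteins.

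For 97.8% of genes the 95% interval of this difference lay within 2-fold in either direction, and 508 genes had an unadjusted p under 0.05, where 897 would by chance. The call of MTATP8P1 was lost under the stricter filter, which excludes the gene, with a replicate block (0.0508), a term for replicate A (0.0919), the groups compared alone (0.79), only replicates B and C, and on leaving out any of the 6 libraries but BRCA2 siRNA replicate B. Its difference hardly moved: -1.39 with the block, with the term and in the groups alone, -1.44 with only replicates B and C, and 0.923 to 1.08 times that value without any 1 library. The 3 libraries of each siRNA with EGF differed among themselves, and the B minus C difference shared by both siRNAs (correlation 0.76) is part of the residual spread of this test. The within-group differences had a standard deviation of up to 0.48, between control replicates B and C, against 0.25 between BRCA2 siRNA replicates B and C without EGF. Across genes the BRCA2 siRNA effects with and without EGF had a Pearson correlation of 0.15 (jackknife error 0.201) and a Spearman correlation of 0.17. The correlation was 0.06 within replicate A and 0.14 within replicates B and C.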

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

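The tests of mixed RNA, of the centring and of exchanged labels with and without EGF were chosen after the results were seen, and the tests of a single deviating control library and of a decrease hidden by cycling were set out before theirs. The results below stood out because the EGF withdrawal effect differed between the siRNA labels by the interaction test in limma, 595 genes in all. The count was 0 when control replicate A with EGF, control replicate A or C without EGF, or BRCA2 siRNA replicate C with EGF was left out (limma; 2684 to 3400 genes at unadjusted p under 0.05). The calls below rest on these libraries. Without any 1 library the values of the named genes were 0.821 (SERPINB13) to 1.22 times (KLK7) those with all libraries. Without the 4 libraries above, in the order given, the interaction was -3.27, -3.42, -3.23 and -3.25 for GPNMB (-3.32 with all libraries) and 1.80, 1.98, 1.79 and 1.88 for MARCHF4 (1.89). With only replicates B and C some values were smaller, such as PDK4 (-1.45, against -2.53), YPEL2 (-0.76, against -1.23), INSC (1.20, against 1.77), CCNG2 (-0.55, against -0.80) and CDC45 (0.66, against 0.93). Values are interactions on the log2 scale, withdrawal with BRCA2 siRNA minus withdrawal with control siRNA, and for the named genes the adjusted p was under the threshold.

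Among the lists with a camera call, the median interaction was positive for ATF4 and unfolded protein response (0.66), mitosis (0.59), DNA replication (0.48), replication-dependent histones (0.40), mitochondrially encoded mRNAs (0.37), homologous recombination (0.28), glycolysis (0.25) and sterol synthesis (0.20). It was negative for cornified envelope genes (-1.06), FOXO targets (-0.68), basal markers (-0.44), interferon-stimulated genes (-0.43) and ribosomal proteins (-0.28). With an estimated correlation the adjusted p of these 13 lists was 0.16 to 0.68. The sterol call was lost under the stricter filter (adjusted p = 0.151), quantile normalization (0.19), robust moderation (0.0506) and only replicates B and C (0.0991), and the mitochondrial call under quantile normalization (0.0689). With no filter the median was -0.36 for cornified envelope genes and -0.26 for interferon-stimulated genes, and with a replicate block it was 0.41 for sterol synthesis.

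Positive interactions in cell cycle genes were CDC20 1.04, CDC6 and CDC45 0.93, PLK1 0.78, UBE2C 0.77, AURKA 0.70 and CCNB2 0.66. In growth factor and cytokine targets they were ETV4 and SPRY4 1.59, ETV5 1.47, FOSL1 1.31 and CSF3 1.13, while FOSB, of the same MAPK list as ETV4, was negative at -1.87. The MAPK list had 4 positive and 2 negative members past the threshold (4 and 2 adjusted over the list alone) and no camera call (adjusted p = 0.20). In metabolism and stress genes they were BCAT1 1.84, ANGPTL4 1.43, ATF4 0.95, PFKP 0.64, HK2 0.55 and PDIA4 0.54. The remaining positive ones were MARCHF4 1.89, KIAA1549L 1.78, INSC 1.77, PDE2A 1.69 and the pseudogene transcript RPSAP52 1.53.

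Negative interactions in keratinocyte and basal genes were DSG1 -3.07, KLK7 -2.54, TRIM29 -2.42, SERPINB13 -2.37, KRT4 -2.00, KRT16 -1.98, KRT15 -1.94, TGM1 -1.79, DSG3 -1.62, DSC3 -1.17, DSC2 -1.06 and KRT6A -0.73. In FOXO and p53 targets they were PDK4 -2.53, FBXO32 -1.81, PIK3IP1 -1.77, YPEL2 -1.23, BTG2 -0.93 and CCNG2 -0.80. In interferon-stimulated genes they were RSAD2 -1.58, IFI44L -1.57, IFIT2 -1.28 and SAMD9L -0.75. In matrix, stromal and vascular genes they were KDR -2.07, NID1 -2.01, DCN -1.07 and COL5A2 -0.97. The remaining negative ones were GPNMB -3.32, EPHB6 -3.26, CYP1A1 -2.69, CA2 -2.63, HPGD -2.57, PPFIBP2 -2.28, PRODH -2.09, MAL2 -2.01, APOE -1.75 and the luminal keratin KRT8 -0.76.

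The weaker withdrawal response in the libraries labelled BRCA2 siRNA was weighed first. Centring of replicate A as the whole source is argued against by the 500 genes that passed with a term for replicate A, against 595 without it, and a single deviating control library is argued against by slopes of 0.37 within replicate A and 0.58 within replicate C, both below the 0.8 that it would need. RNA from EGF-grown cells mixed into the libraries without EGF would dilute rises and falls by the same share. The genes changed at least 2-fold in the control libraries of the replicate used for the choice. They also had a mean above the median and passed the control withdrawal test in the fit of all libraries. The share was solved with the other control replicate without EGF, which that test had used too, so the choice was not independent of it. For genes chosen in replicate A the share was 0.386 (95% interval 0.373 to 0.398) from those that fell. It was 0.606 (0.585 to 0.630) from those that rose, a difference of 0.22. Chosen in replicate C the shares were 0.461 (0.429 to 0.482) and 0.655 (0.632 to 0.676), a difference of 0.195. These intervals, from resampling genes, did not overlap in either choice, but genes are not independent replicates. The differences lie around the bound of 0.2. That both choices of genes must exceed it was required only after 0.22 was seen. A single share of 0.53 left 69 of the 2312 genes with a 2-fold control response departing from it after adjustment. A share of 0.44 left 8 of the 804 with a mean above the median, and 140 at unadjusted p under 0.05 in a t test. A single share would shrink every rise and fall. Yet TENM2, SEMA3A and RGS2 had interactions of 0.00, -0.01 and -0.00, with changes of 2.20, -2.27 and -1.78 with BRCA2 siRNA. A single share as the whole source is therefore argued against for these genes, which were named for large changes with BRCA2 siRNA. Weakly expressed genes may be compressed by the unknown transform behind the log2 values. Mixed RNA would act on all genes of a library at once, so mixing alone would not spare TENM2, SEMA3A and RGS2. As a part of the source, mixed RNA cannot be told apart from a weaker response in all cells. An effect of the siRNA on the response to EGF withdrawal, the difference that the design names, stays open as well, and rests on 2 control libraries and on libraries in which BRCA2 was not lower.

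The lack of a lower BRCA2 in the libraries labelled BRCA2 siRNA was weighed next. Labels exchanged between siRNAs with EGF are argued against as the reason. The 6 libraries lay within 0.348 of each other, under the 0.5 that a knocked-down library under either label would need. If no knockdown was present at harvest, the libraries would lie together under either labelling. The range then cannot decide whether labels were exchanged. A decrease hidden by more cycling cells without EGF is argued against too: BRCA2 lay at percentile 75 of the 72 other replication and recombination genes, whose differences had a median of 0.59 and quartiles of 0.34 and 0.72, where that explanation needs it below percentile 5. Labels exchanged without EGF cannot be told apart from a difference that BRCA2 shares with these genes, since percentile 75 lies between the 50 and 95 that would decide; with such an exchange BRCA2 without EGF would be -0.74, every siRNA effect without EGF would turn its sign, the interaction would turn for 592 of the 595 genes (GPNMB from -3.32 to 3.09), and the slope of the withdrawal effects would be 1.27 instead of 0.49, a stronger response with BRCA2 siRNA. MTATP8P1, the 1 gene called between siRNAs with EGF, was called lower with BRCA2 siRNA without EGF too. An exchange without EGF would turn that sign. A single gene with values near the filter minimum of 3.32 cannot decide this. The time from transfection to harvest is not given in the sources used here, and BRCA2 protein was not measured, so a decrease before harvest stays untested.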

How the results depend on the processing

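The term for replicate A, the use of only replicates B and C, and the residual component were chosen after seeing the data. No result past its threshold changed sign under any setting tried. The pseudocount of 8 and DESeq2 were not run, because the values are on a log2 scale without counts; depth, unknown here, may limit genes near the floor. Counts in the 4 pairwise comparisons and the interaction stayed within 1.5 times under no filter, both rescalings (interaction 609 with median-of-ratios, 741 with quantile normalization) and robust moderation. The BRCA2 siRNA effect with EGF went from 1 gene to 0 under the stricter filter (which excludes MTATP8P1), the replicate block, the groups compared alone, the term for replicate A and only B and C; for the others the cause was not tested. The replicate block gave 930 interaction genes, and the cause was not tested. For BRCA2 siRNA without EGF 6776 genes passed in the groups compared alone, a fit that leaves out the libraries with EGF. The standard deviation of B minus C was 0.48 and 0.43 with EGF, against 0.25 without in BRCA2 siRNA libraries. The spread shared by all groups in the main fit takes in the wider B minus C difference with EGF. Single genes differed in this. GPNMB had a standard deviation of 0.79 in BRCA2 siRNA libraries without EGF, against 0.25 (control) and 0.29 (BRCA2 siRNA) with EGF. For GDF15 these values were 0.22 against 1.26 and 1.00. Of 15 same-letter pairs of libraries, the B pair and the C pair across siRNAs with EGF had residual correlations of 0.70 each. The others ran from -0.37 to 0.04. Pairs of A libraries cannot tell whether A shared a deviation, since the centring of A against B and C removed it. Only B and C, with fewer libraries, gave 2074 genes for withdrawal with control siRNA, 47 with BRCA2 siRNA, 0 for BRCA2 siRNA without EGF and 0 for the interaction, and BRCA2 without EGF at 0.54 (adjusted p = 0.382). The residual component gave 58, 7492, 8745 and 4342 genes for BRCA2 siRNA with and without EGF, withdrawal with BRCA2 siRNA and the interaction; it is derived from the same residuals, so these counts are too high.

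Leaving out each library gave 0 to 1 genes for BRCA2 siRNA with EGF, 624 to 3595 without, 6164 to 10023 for withdrawal with control siRNA, 2228 to 4800 with BRCA2 siRNA and 0 to 1606 for the interaction. A lone library left in a group is assumed to vary like the others. BRCA2 changed by -0.06 to 0.11 with EGF and by 0.64 to 0.84 without (adjusted p = 0.0655 at 0.64). Of the named genes past the threshold, leaving out a library ended 16 of 59 calls for BRCA2 siRNA without EGF, 1 of 63 for withdrawal with control siRNA, 8 of 53 with BRCA2 siRNA and 48 of 48 for the interaction. Of 110 list tests 59 passed at the preset correlation and 0 with an estimated correlation; other settings ended 37 calls and added 28, counted over settings. Sizes moved by over 1.5 times in places: on withdrawal with control siRNA quantile normalization took CALR from -0.69 to -0.40, H1-2 from -0.86 to -0.56 and ERBB3 from 0.80 to 0.44, and with BRCA2 siRNA it took ATF4 from -0.50 to -0.28, PDIA4 from -0.35 to -0.19, H1-2 from -0.47 to -0.24, RPS20 from -0.33 to -0.14 and the mitosis median from -0.33 to -0.21. With no filter, which adds weakly expressed members, the cornified envelope median went from 2.34 to 0.68 with control siRNA and from 0.64 to 0.21 with BRCA2 siRNA; the stricter filter took the latter to 1.20. Only B and C ended 8 of 63 named calls for withdrawal with control siRNA, 44 of 53 with BRCA2 siRNA, and all 59 for BRCA2 siRNA without EGF and all 48 for the interaction.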

Other observations

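The comparison of replicates B and C, its list tests and the residual component were chosen after the data were seen; the splits of the libraries and the test of partial EGF depletion were set out before their results. Among the libraries with EGF, replicates B and C differed in both siRNA groups alike. With siRNA as a term in limma, 5559 genes differed, 3020 higher in B and 2539 higher in C. The 2 libraries of a letter come from a single replicate with different siRNAs. The errors, counts and p values of this comparison therefore measure scatter between siRNAs within a letter, not variation between replicates. Stress response genes were higher in B: 23 of 27 members of the ATF4 and unfolded protein response list (23 adjusted over the list alone), such as the chaperone DNAJB9 (2.04 ± 0.11, n = 2 and 2), the stress factors DDIT3 (1.86) and ATF3 (1.91), and CHAC1 (1.44). So were 16 of 18 NF-kB and cytokine genes (16 adjusted over the list alone), with the cytokines IL6 at 2.66 ± 0.26 and IL1A at 2.16, and 8 of 12 EGF receptor family genes (8 adjusted over the list alone), with the ligands HBEGF at 2.60 and EREG at 1.54. Of 23 basal markers 13 were higher in B and 0 in C (14 and 0 adjusted over the list alone), with a median of 0.40. DNA replication and sterol synthesis genes were higher in C: 34 of 37 DNA replication genes, with MCM10 at -1.53 and MCM3 at -1.37 for B minus C, 19 of 25 sterol synthesis genes, with HMGCS1 at -2.48 ± 0.15 and IDI1 at -2.06, 17 of 25 histones and 20 of 35 homologous recombination genes (35, 19, 18 and 24 adjusted over each list alone). Some members went the other way: 3 homologous recombination genes and 2 histones were higher in B, and 1 EGF receptor family gene was higher in C (4, 2 and 2 adjusted over each list alone). These lists passed camera at the preset correlation (adjusted p from 2.9e-24 to 0.00021), and the adjusted p was 0.40 for each with an estimated correlation. Of 33 mitosis genes 13 were higher in C and 3 in B (14 and 3 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.0036; adjusted p = 0.40 with an estimated correlation).

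Across genes the B minus C difference had a correlation of 0.76 between the siRNA groups with EGF. In BRCA2 siRNA libraries it had a correlation of -0.01 between the media, and its standard deviation was 0.43 with EGF and 0.25 without. The first principal component of the model's residuals held 52.3% of the residual variance, with the 5 libraries without EGF within 0.128 of 0 and the libraries with EGF between -1.63 and 1.85. Partial loss of EGF in one of the replicates was tested as a hypothesis: the B minus C difference had a correlation across genes of -0.30 with the withdrawal effect under control siRNA and of -0.37 with that under BRCA2 siRNA. Taken in the control libraries alone it had -0.30 with the withdrawal effect under control siRNA, and in the BRCA2 siRNA libraries alone -0.27. The negative sign would make C the replicate short of EGF. The lists went both ways on this, set against withdrawal with control siRNA. ATF4, NF-kB and MAPK genes, lower in C, went with it. DNA replication, histone, sterol synthesis, homologous recombination and mitosis genes, higher in C, and basal markers, higher in B, went against it. The correlations are short of the 0.5 that partial loss would need and not below 0.3 in size in both groups. Partial loss of EGF may thus contribute and cannot be told apart from another difference in culture.

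The 6 libraries of a 3 against 3 comparison make 10 splits, too few for a share under 0.05. For the siRNA comparison with EGF the real split gave 1 gene and 2 splits, the real one included, gave as many; the highest other gave 5547. That split set control replicates A and B and BRCA2 siRNA replicate B against BRCA2 siRNA replicate A and both C libraries, so it follows the difference between B and C and points to a structure of the samples. A replicate block gave 0 genes for this comparison, but it sets the same letter effect in both media. The B minus C difference in BRCA2 siRNA libraries had a correlation of -0.01 between the media, so the block cannot fully remove it. Pairing by letter within the libraries with EGF alone is not reported here, so whether it would change the count stays open. For withdrawal with BRCA2 siRNA the real split gave 4871 genes, 1 split, the real one itself, gave as many, and the highest other gave 0. The other splits mix libraries with and without EGF within a group, so the withdrawal effect widens their spread. Low counts there were built in and decide nothing.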
